A study of Mus musculus with 146 samples.

How the data were processed

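The series measured mRNA by sequencing in mice that carry an HA-tagged ribosomal protein (RPL22-HA) switched on in Cx3cr1-expressing cells, which in the brain are mainly microglia. All mice received tamoxifen by gavage, per the labels' protocols, to activate the Cre recombinase. Brains were homogenised with cycloheximide, which holds ribosomes on mRNA. Part of the cleared homogenate was kept as the input, and the rest was incubated with an anti-HA antibody or with mouse IgG1 as an isotype control. The anti-HA libraries thus hold ribosome-bound mRNA of tagged cells, the IgG libraries hold the background of the procedure, and the inputs hold RNA of the whole homogenate. T cells were sorted from whole brain by CD25. PolyA-tailed RNA was captured before library preparation, per the labels' protocols.

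Samples were grouped by their titles. The 99 libraries of the disease course cover 6 stages of relapsing-remitting experimental autoimmune encephalomyelitis (EAE), a mouse model of multiple sclerosis, with an anti-HA, an IgG and an input library for each numbered replicate. A further 24 libraries compare microglia of Ifngr ko/fl with Ifngr ko/wt mice, and 23 hold sorted T cells of both genotypes. The labels do not say whether replicates came from separate animals, so p-values from values per library measure only the spread between these libraries. The titles of the Ifngr libraries name EAE but no stage.

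In 3 of the 4 tables the deposited values per library have the unit signal, gene counts divided by a size factor of the library; the unit was read from the values, since neither labels nor headers state it. Every value of a column was a whole multiple of 1 step, taken as 1 read, in 100% of values, to within 0.01 of a step plus 1e-07 of the multiple. The size factors put the libraries of 1 table on a common scale, so values were compared only within a table. The design assumed raw counts and edgeR as the main test; because the deposited values are normalized, limma on a log scale was used instead. The log2 fold changes in the authors' deposited tables and the adjusted p-values beside them were made by the authors with a tool not given in the sources used here, per the file headers. The clusters column is another kind of value, a group number the authors gave each gene, per the file headers. Reads were mapped to mm10, per the submitters' processing notes; the aligner, the counter and the annotation are not given in the sources used here, nor is whether counting used strand.

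Each of the 3 tables of libraries holds only genes that the authors chose on those same libraries. All 716 genes of the stage table pass an adjusted p of 0.05 and a 2-fold change in at least 1 of the 15 comparisons between anti-HA groups in the authors' deposited columns. There are 204 genes in the Ifngr microglia table and 85 in that of the T cells. All 85 pass an adjusted p of 0.1 between genotypes of CD25pos cells in the authors' deposited columns, and 15 pass 0.05. A count of called genes is therefore a count within a chosen list. It is no independent evidence that a group differs, and no fixed gene list was tested against other genes in those tables. The fourth table holds the authors' statistics for 8627 genes of CD25pos T cells, with no values per library.

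Before the data were examined, the groups, 21 comparisons, 41 gene lists, the rule for named genes and most alternative settings were fixed. Each comparison was fitted with limma 3.58.1 in R 4.3.3 on log2(value + 1), with the libraries of all groups of the table sharing 1 estimate of the spread (anti-HA libraries only for comparisons between stages or microglial genotypes). Fold changes on this scale understate the change of genes with low values. P-values are two-sided and Benjamini-Hochberg adjusted over the genes of the table; a gene is called at an adjusted p below 0.05. Errors of log2 fold changes are standard errors, and group values are means ± SD. A library's score for a gene list is its mean log2(value + 1) over the list. In the table of 8627 genes, lists of at least 3 measured genes were tested with limma's cameraPR at a preset correlation of 0.01; a correlation cannot be estimated without values per library. Each list's median was also placed among 10000 random lists of equal size, not matched on expression because the table holds no mean.

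Named genes follow a rule with 3 parts. The first takes the 6 highest and 6 lowest log2 fold changes among called genes whose mean in either group reaches the table's median, without predicted models and sex-linked list genes. The second takes up to 4 members of each list with at least 3 measured genes, by smallest p, or the 2 with the highest mean where none passed. The third takes a fixed set of genes wherever they were measured. The rule named 1106 gene results. The text prints a part of them, 323 results on 116 genes, picked after the values were seen; counts of calls lost without 1 library are given over all that the rule named. Kat5, Setd5 and Rbfox3 as examples of the interaction in T cells, and Rpl39 and Gpr34 as a pair, were singled out after their values were seen.

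The alternative settings fixed then were quantile normalization of the log values, pseudocounts of 0.1 and 10, a filter at the 25th percentile of gene means, limma with trend and robust settings, library weights, fits of only the groups compared, the replicate number as a block, an adjusted p of 0.01, a fold of at least 2, and leaving out each replicate in turn. Chosen after seeing the data were edgeR 4.0.16's quasi-likelihood test on the recovered reads, fits without libraries that stood apart or held the fewest reads, and a term for a split seen in the input libraries. Replicate numbers in the titles were tested as pairs. Deviations from the group means of same-numbered anti-HA and input libraries correlated at 0.15 to 0.596 over 4 pairs at initiation, 0.224 to 0.45 over 6 pairs at max and 0.138 to 0.386 over 8 pairs in remission, all above 0.1, so the numbers were taken to pair these libraries. The block moved none of those counts by over 1.5 times.

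Among 331 pairs of libraries within groups, none held identical values, and the lowest chi-square per degree of freedom was 1.33, so no library was counted as a duplicate. On simulated values for 716 genes, limma recovered 53% of 2-fold and 96% of 4-fold changes at the group sizes of initiation against non-immunized mice. The shares were 52% and 100% over 204 genes for Ifngr microglia and 50% and 90% over 85 genes for CD25pos T cells. All simulated genes had the same dispersion, so the shares do not hold for genes with a larger spread. The list test found 100% of lists of 30 genes shifted by 1 on the log2 scale and 2% of unshifted ones. Those lists were drawn from shuffled values, and shorter or correlated lists were not simulated. Positions are from GENCODE vM21 on the mouse assembly GRCm38, the Genome Reference Consortium's name for mm10; 696 of 716, 202 of 204, 83 of 85 and 8485 of 8627 symbols matched it. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. IgG libraries entered the fits of anti-HA against input through the shared spread and otherwise served as measured background; no comparison against them was tested. Reads that a gene shares with a near-identical copy cannot be separated in these tables; the annotation holds 1 pseudogene named for Rpl39.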

Results

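Ribosome-bound mRNA of Cx3cr1-lineage brain cells was profiled over a relapsing-remitting course of experimental autoimmune encephalomyelitis, with the isotype background and the whole homogenate of the same numbered replicates. The anti-HA groups held 6 libraries of non-immunized mice, 4 of initiation, 6 of max, 8 of remission, 5 of cure and 4 of relapse, and the IgG and input groups had the same sizes. A second set compared microglia of Ifngr ko/fl and ko/wt mice, with 4 anti-HA, 4 IgG and 4 input libraries per genotype. Another set held T cells from the brain: 6 ko/wt and 6 ko/fl CD25neg libraries, and 5 ko/wt and 6 ko/fl CD25pos libraries. CD25, the interleukin-2 receptor alpha chain, is high on regulatory T cells and on recently activated ones.

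Read totals over the chosen genes, which reflect enrichment as well as depth, differed widely between libraries. Over the 716 genes of the stage table, anti-HA libraries held 152704 to 880410 reads (median 386600), inputs 49902 to 159540 (median 92244) and IgG libraries 6775 to 162205 (median 37974), taking the step of each column as 1 read. Over the 204 genes of the Ifngr microglia table, anti-HA libraries held 136064 to 589041 reads and IgG libraries 4360 to 17987. Over the 85 genes of the T cell table, CD25neg libraries held 1049 to 3443 reads and CD25pos libraries 608 to 3292, so single T cell values rest on few reads. These are totals over chosen genes, not library sizes.

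Whether the anti-HA precipitate carried the mRNA of tagged cells was examined by comparing it with the input. The chosen genes hold 0 markers of neurons, astrocytes, oligodendrocytes, T cells or B cells from the fixed lists. Enrichment of microglial genes could thus be seen, but not depletion of those other cells. In non-immunized mice, homeostatic microglial genes were far higher in the anti-HA libraries: all 11 measured members of the list were called, with a median log2 fold change of 5.19. Selplg, which encodes P-selectin glycoprotein ligand 1, reached 17500 ± 4537 (SD, n = 6) in anti-HA libraries, 104.8 ± 20.1 in inputs and 90.7 ± 18.6 in IgG libraries, a log2 fold change against input of 7.34 ± 0.23 (limma, adjusted p 6.39e-46). The purinergic receptor gene P2ry12 (chromosome 3, 59216272 to 59262871, minus strand) was higher by 4.58 ± 0.46, the Fc receptor-like gene Fcrls by 6.73 ± 0.37, Cst3, which encodes cystatin C, by 4.69 ± 0.21 and the glycoprotein gene Gp9 by 7.02 ± 0.40. Border macrophage genes were also higher, Pf4 by 5.86 ± 0.33 and Cbr2 by 5.47 ± 0.36. Of 716 genes, 588 were higher and 10 lower in the precipitate, the lower ones including Fabp5 (-2.11 ± 0.52), a fatty acid binding protein gene, and the opioid precursor gene Pdyn (-1.44 ± 0.26). Quantile normalization, which forces equal distributions on all libraries, lowered the log2 fold changes by a median of 2.36 and gave 216 higher and 289 lower. Run on chosen genes only, it removes a change that most of them share. A call lost or turned under it cannot tell a scaling effect from such a change.

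The enrichment held at each stage, with 674 genes higher and 1 lower at initiation, 669 and 2 at max, 685 and 0 in remission, 597 and 0 in cure, and 613 and 0 in relapse. Quantile normalization gave 182 and 205, 199 and 213, 237 and 271, 208 and 258, and 193 and 243, with median shifts of 2.65, 2.34, 2.48, 2.07 and 2.15. Selplg was higher in the precipitate by 5.22 ± 0.29 at initiation, 5.06 ± 0.23 at max, 5.56 ± 0.20 in remission, 5.42 ± 0.26 in cure and 5.17 ± 0.29 in relapse. P2ry12 exceeded the input by 2.68 ± 0.57 at initiation, 2.65 ± 0.40 in remission, 2.95 ± 0.51 in cure and 3.37 ± 0.57 in relapse; quantile normalization ended the calls at initiation (0.12), in remission (0.18) and in cure (adjusted p 0.0561). At max its excess was only 1.10 ± 0.46 (adjusted p 0.022), which was lost without anti-HA library 3 (adjusted p 0.0566), 4 (0.0639) or 5 (0.0576) and with a pseudocount of 0.1 (0.0901), and turned to -1.21 under quantile normalization. All 11 homeostatic genes were still called higher at max (median 3.02), but under quantile normalization only 5 were, with P2ry12, Gpr34, Sparc, Cst3 and Adgrg1 turning negative. All 7 border macrophage genes were higher at max too (median 3.73, 6 under quantile normalization). The chemokine gene Cxcl10 did not differ at max (1.28 ± 0.65, adjusted p 0.0553). It turned to -1.10 under quantile normalization, and passed the threshold without anti-HA library 6 (0.0389) or input 2 (0.0235) and with the replicate block (0.000148).

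At the initiation of disease, interferon-response, antigen-presentation and cell-cycle genes rose together in microglia, while the homeostatic genes fell. The acute-phase gene Saa3 (chromosome 7, 46711998 to 46715700, minus strand) went from 32.9 ± 13.7 (SD, n = 6) in non-immunized mice to 6844 ± 2707 (n = 4), a log2 fold change of 7.67 ± 0.56 (adjusted p 1.9e-12). The monocyte-attracting chemokine gene Ccl2 rose by 6.19 ± 0.69, the complement factor gene Cfb by 5.83 ± 0.64 and the nucleic acid sensor gene Zbp1 by 5.74 ± 0.52. All 16 measured interferon gamma response genes rose (median 3.68), among them the guanylate-binding protein gene Gbp2 by 6.17 ± 0.63 and the chemokine gene Cxcl10 (chromosome 5, 92346638 to 92348889, minus strand) by 5.67 ± 0.65. All 14 type I interferon genes rose (median 3.16), including Irf7 (3.94 ± 0.40) and Isg15 (3.71 ± 0.44). So did all 16 MHC class I genes (median 2.12), led by the class I transactivator gene Nlrc5 (5.58 ± 0.40), with the peptide transporter gene Tap1 at 3.55 ± 0.39 and H2-K1 at 2.97 ± 0.28. Of 11 MHC class II genes, 9 rose and 1 fell; H2-Aa (chromosome 17, 34282744 to 34287823, minus strand) went from 1224 ± 454 to 8331 ± 9780, a log2 fold change of 2.20 ± 0.51 (adjusted p 0.000275). Initiation 2 carried much of this mean, at 22870, and without it the log2 fold change was 1.495, still called.

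All 16 proliferation genes rose at initiation (median 3.66): the cycling marker gene Mki67 by 4.28 ± 0.77 (1.27 ± 1.38 against 54.4 ± 56.7, adjusted p 1.77e-05), the topoisomerase gene Top2a by 4.06 ± 0.76 and the mitotic kinesin gene Kif11 by 4.17 ± 0.67. Of 13 chemokine genes 11 rose and 1 fell, and of 10 disease-associated microglia genes 9 rose, such as Cst7, an endosomal cystatin gene (3.26 ± 0.46), and the galectin gene Lgals3 (3.05 ± 0.45). Apoe did not change at this stage (0.03 ± 0.28, adjusted p 0.919). Its sign turned with library weights (-0.22) and without initiation 2 (-0.38), non-immunized 5 (-0.0044) or non-immunized 6 (-0.033). All 11 homeostatic genes fell (median -1.48). P2ry12 dropped from 518.4 ± 146 to 110.8 ± 51.8 (-2.29 ± 0.54), the receptor gene Gpr34 fell by 4.07 ± 0.63 and the TGF-beta receptor gene Tgfbr1 by 1.51 ± 0.32. Of 7 border macrophage genes 2 rose and 1 fell, Pf4 by 1.68 ± 0.35. Adjusted over the list alone, these counts were equal except for chemokines (12 up and 1 down); since the authors chose the genes on these libraries, neither count is independent evidence.

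In all, 533 genes were higher and 116 lower at initiation, by limma. Quantile normalization lowered the fold changes by a median of 1.17 and gave 199 higher and 173 lower: 15 of 16 interferon gamma genes, 11 of 14 type I genes, 12 of 16 MHC class I genes, 12 proliferation genes and 10 homeostatic genes kept a call, but only 3 disease-associated genes did, with Itgax and Lyz2 turning negative, and 5 border macrophage genes fell, with Cd163 and F13a1 turning negative. The MHC class II count became 6 higher and 1 lower, and the class I gene Erap1 turned negative. Of 75 called genes that the naming rule picked, 7 lost their call without 1 library. Among them was Spp1, which encodes osteopontin. Its rise of 1.55 ± 0.74 (adjusted p 0.0473) was lost without any of the 4 initiation libraries or non-immunized 1, 2, 3, 4 or 6 (adjusted p 0.0574 to 0.121), under quantile normalization and by edgeR (0.0959).

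At the maximum of disease antigen-presentation and disease-associated genes were again higher than in non-immunized mice, and homeostatic genes lower. Saa3 reached 14440 ± 6492 (n = 6), a log2 fold change from non-immunized mice of 8.69 ± 0.50 (adjusted p 4.66e-15), against 1045 ± 413 in the inputs and 356.5 ± 183 in the IgG libraries of that stage. The chemokine gene Ccl5 rose from 60.7 ± 24.1 to 6142 ± 2203 (6.64 ± 0.42), the complement gene C3 from 22.3 ± 6.92 to 1881 ± 365 (6.36 ± 0.39), Ccl8 by 6.32 ± 0.51 and Cfb by 7.22 ± 0.58. All 16 interferon gamma genes rose (median 4.11), among them the T cell-attracting chemokine genes Cxcl9 (chromosome 5, 92321347 to 92328079, minus strand) by 5.15 ± 0.64 and Cxcl10 by 5.98 ± 0.58, and all 14 type I genes did (median 3.09). Of 11 MHC class II genes, 10 rose and 1 fell; Ctss, a lysosomal protease gene, turned sign under quantile normalization. H2-Aa rose to 24710 ± 9604 (4.33 ± 0.45), the invariant chain gene Cd74 from 1514 ± 966 to 29150 ± 16760 (4.28 ± 0.53) and the class II transactivator gene Ciita (chromosome 16, 10480059 to 10528418, plus strand) by 4.44 ± 0.51. H2-Aa in the IgG libraries was 60.1 ± 38.4 in non-immunized mice and 1052 ± 670 at max, and in the inputs 30.2 ± 12.0 and 1587 ± 569. The co-stimulatory receptor gene Cd40 rose by 4.80 ± 0.42 and Cd274, which encodes the checkpoint ligand PD-L1, by 3.52 ± 0.39.

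All 10 disease-associated genes rose at max (median 2.46): Cst7 from 50.0 ± 12.3 to 1185 ± 426 (4.49 ± 0.41), the receptor kinase gene Axl by 2.94 ± 0.28, Apoe from 34330 ± 7082 to 101200 ± 18340 (1.56 ± 0.25) and Spp1 (chromosome 5, 104435118 to 104441050, plus strand) from 74.2 ± 75.0 to 482.9 ± 383 (2.65 ± 0.66), a call that quantile normalization ended (adjusted p 0.0564). All 11 homeostatic genes fell (median -1.94), P2ry12 to 56.3 ± 30.5 (-3.36 ± 0.48), Fcrls from 2850 ± 818 to 287.3 ± 211 (-3.59 ± 0.46) and Cst3 by 1.77 ± 0.28. Gp9 fell from 580.4 ± 177 to 38.9 ± 19.7 (-3.97 ± 0.41, adjusted p 6.65e-10). Border macrophage genes moved apart, 2 higher and 5 lower, with Pf4 at -1.58 ± 0.31 and Lyve1 at -1.61 ± 0.41. Cell-cycle genes were called for 12 of 16 (median 2.06), Mki67 at 2.16 ± 0.69, but none of them under quantile normalization, where Mki67 stood at -0.019. In total 512 genes were higher and 123 lower; quantile normalization, with a median shift of 1.10, gave 208 and 188, and kept 16 interferon gamma, 12 type I, 11 MHC class I, 9 class II and 7 disease-associated genes higher and 11 homeostatic genes lower. It turned Erap1, Irf9, Ctsl, Mcm3, Mcm6, Cd163 and F13a1 as well. Adjusted over the list alone, the list counts did not change. Of 76 called genes under the naming rule, 1 lost its call without 1 library.

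In remission the shift from the non-immunized state remained large. H2-Aa stood at 20750 ± 7144 (n = 8, log2 fold change from non-immunized mice 4.07 ± 0.43, adjusted p 1.93e-09) and Cd74 was up by 4.18 ± 0.50. Saa3 was at 2650 ± 1681 (6.08 ± 0.47), C3 at 991.7 ± 333 (5.39 ± 0.37), Ccl5 at 2634 ± 1138 (5.36 ± 0.40), and the B cell-attracting chemokine gene Cxcl13 was up by 5.88 ± 0.46. All 16 interferon gamma (median 2.87), 14 type I (2.40), 16 MHC class I (1.66) and 10 disease-associated genes (2.12) were higher, as were 10 of 11 MHC class II genes (2.19) and 12 of 13 chemokine genes. Apoe was at 111600 ± 35030 (1.67 ± 0.23), Itgax, an integrin gene, at 3.22 ± 0.32 and Spp1 at 2.98 ± 0.62. Homeostatic genes were lower for 9 of 11 (11 adjusted over the list alone, median -1.05), P2ry12 at 216.0 ± 143 (-1.54 ± 0.45) and Fcrls at 698.2 ± 140 (-1.99 ± 0.43). Of 7 border macrophage genes 4 fell, Lyve1 by 1.72 ± 0.39. Proliferation genes were called for 9 of 16, none of them under quantile normalization, where Mki67, also not called with a pseudocount of 10 (0.0983), went from 1.70 ± 0.65 to -0.31 and Kif11 from 2.10 ± 0.56 to -0.048. Their list score was uneven: 5.98 to 6.31 in remission 1, 2, 3 and 5, and 4.42 in remission 4. Remission 6, 7 and 8, at 3.18 to 3.56, lay below the non-immunized mean of 3.69. The totals were 445 higher and 110 lower, or 174 and 194 after quantile normalization (median shift 0.81), under which the class I genes Psmb10 and Erap1 turned negative and 16, 12, 12, 9 and 9 genes of the 5 lists stayed higher. Of 75 called genes under the naming rule, 2 lost their call without 1 library.

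The stage labelled cure was not a return to the non-immunized pattern. Cxcl13 was at 1.80 ± 2.46 (n = 6) in non-immunized mice and 96.5 ± 49.6 (n = 5) in cure, a log2 fold change of 5.39 ± 0.52 (adjusted p 2.88e-09). The heparanase gene Hpse was up by 4.55 ± 0.50, Ccl8 by 4.53 ± 0.54, C3 by 4.11 ± 0.41, Saa3 by 3.80 ± 0.52 and Ccl5 by 3.58 ± 0.45. All 10 disease-associated genes were higher (median 1.44, 10 under quantile normalization): Cst7 by 3.36 ± 0.43, Spp1 by 3.58 ± 0.69 to 1087 ± 1080, Itgax by 2.23 ± 0.36 and Apoe by 0.95 ± 0.26. Interferon gamma genes were higher for 13 of 16 (all 16 adjusted over the list alone, median 2.08), type I genes for 10 of 14 (1.26), MHC class I genes for 12 of 16 (1.10) and class II genes for 7 of 11 (8 adjusted over the list alone, 1.07). Under quantile normalization these counts were 11, 7, 12 and 8. H2-Aa was up by 2.74 ± 0.48 and Cd74 by 2.49 ± 0.56. H2-Ab1 rose by 1.57 (adjusted p 0.0222), lost without cure 1, 4 or 5 or non-immunized 5 (0.05 to 0.0827). No proliferation gene of 16 was called by limma, Mki67 standing at 1.17 ± 0.73 (adjusted p 0.202) and the replication helicase gene Mcm3 at -0.05 (0.901).

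Homeostatic genes were lower in cure for 7 of 11 (8 adjusted over the list alone, median -1.11). Cst3 fell by 1.53 ± 0.29, Selplg by 1.35 ± 0.24 and Fcrls by 1.83 ± 0.49, whereas P2ry12 was not called (-0.79 ± 0.51, adjusted p 0.226). The lectin gene Fcna fell from 296.0 ± 87.8 to 38.4 ± 20.7 (-3.02 ± 0.38), and 6 of 7 border macrophage genes fell, Pf4 by 1.69 ± 0.33 and Folr2, a folate receptor gene, by 1.62 ± 0.35. The totals were 175 higher and 122 lower, or 151 and 162 under quantile normalization (median shift 0.22). All cure libraries lay on 1 side of a split seen in the inputs, with all relapse libraries and remission 7 and 8. Only remission had libraries on both sides, so a term for the side rests on remission 7 and 8 against 1 to 6. Calls that it ends or adds cannot tell a batch from disease stage. With the side as a term, 216 genes were higher and 23 lower, and P2ry12 became called (-2.46, adjusted p 0.0185). Cst3 (-0.97, 0.0992), Selplg (-0.85, 0.0868), Fcrls (-1.90, 0.0685), Pf4 (-1.01, 0.122), Folr2 (-1.39, 0.0658) and Spp1 (2.45, 0.0882) lost their calls. Of 59 called genes under the naming rule, 8 lost their call without 1 library.

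Relapse libraries also stood apart from the non-immunized state. Saa3 was at 2404 ± 1242 (n = 4), 6.08 ± 0.56 above non-immunized mice (adjusted p 8.63e-10), Cxcl13 was up by 5.88 ± 0.55, Ccl8 by 5.63 ± 0.57, the prothrombinase gene Fgl2 by 4.77 ± 0.61 and C3 by 4.68 ± 0.44. All 10 disease-associated genes were higher (median 1.78), with Cst7 at 3.77 ± 0.46, Spp1 at 3.41 ± 0.74 and Apoe at 1.53 ± 0.28. Interferon gamma genes were higher for 15 of 16 (2.29; 9 under quantile normalization), type I genes for 9 of 14 (1.19; 4), MHC class I genes for 13 of 16 (1.40; 12) and class II genes for 9 of 11 with 1 lower (1.45; 7 and 1), H2-Aa by 3.24 ± 0.51 and H2-Ab1 by 1.95 ± 0.59. No proliferation gene was called by limma. Mki67 was at 1.51 ± 0.77 (adjusted p 0.113), but was called without relapse 3 (2.33, 0.0155), by edgeR (2.62, adjusted p 0.041), with library weights (1.66, 0.0173) and with a term for the input split (2.94, 0.0477), and stood at -0.047 under quantile normalization. Homeostatic genes were lower for 7 of 11 (8 adjusted over the list alone, median -1.21), Fcrls by 2.29 ± 0.52 and Selplg by 1.21 ± 0.26, with P2ry12 not called (-0.99 ± 0.54, adjusted p 0.136) except with library weights (0.00561), in a fit of the compared groups alone (0.0127) or with a term for the input split. Of 7 border macrophage genes 4 fell, Pf4 by 2.08 ± 0.35 and Folr2 by 1.99 ± 0.37. The totals were 220 higher and 107 lower, or 146 and 161 under quantile normalization (median shift 0.41). With the side of the input split as a term they were 310 and 33, P2ry12 was called too (-2.66, adjusted p 0.00975), and Selplg (-0.71, 0.133) and Spp1 (2.29, 0.0992) lost their calls. Of 61 called genes under the naming rule, 5 lost their call without 1 library.

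**Figure D1:**
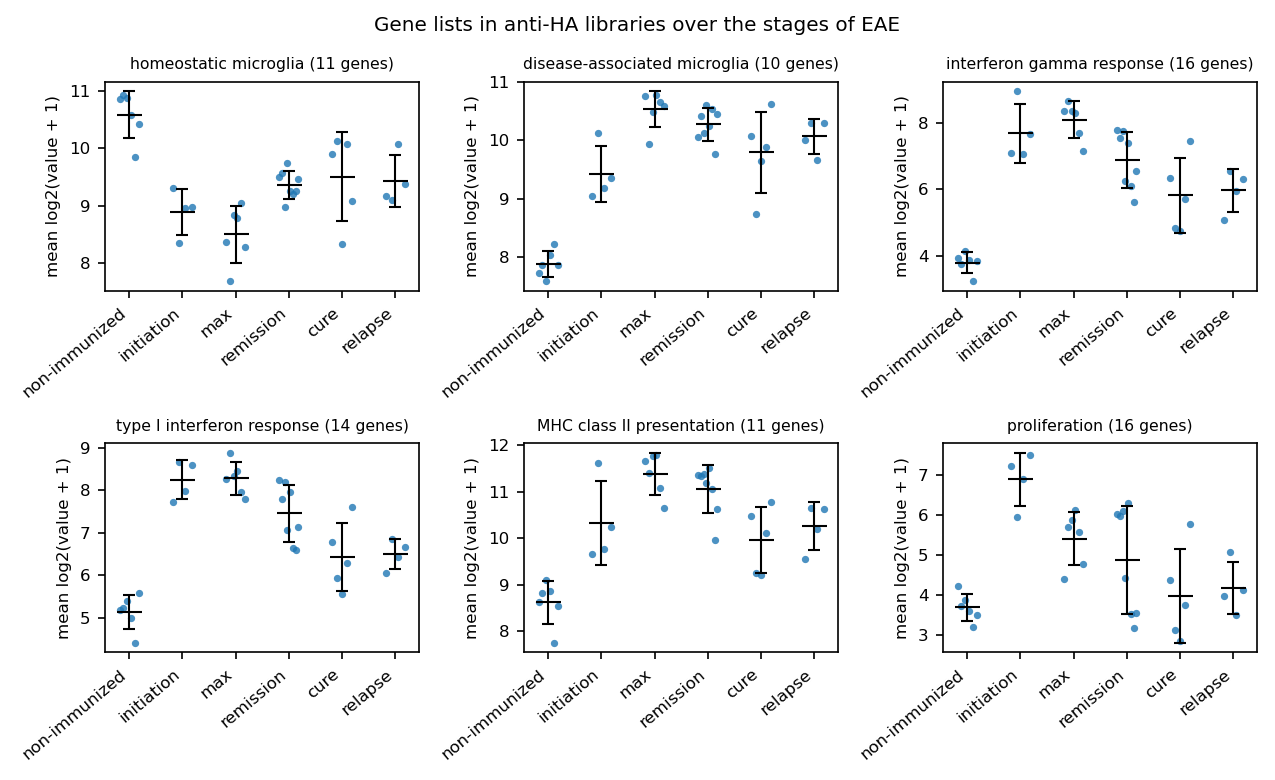
Mean log2(value + 1) over the measured genes of 6 fixed lists (y axes) in anti-HA libraries of the 6 stages (x axes); points are libraries and bars are the mean ± SD. The interferon gamma list went from 3.80 ± 0.30 in non-immunized mice to 8.08 ± 0.56 at max and 5.82 ± 1.12 in cure, and the homeostatic list from 10.6 ± 0.41 to a lowest mean of 8.51 at max.

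Comparing remission with max asked what had changed as disease abated. Part of the interferon-response genes had come down and part of the homeostatic genes had returned. Gp9 was higher in remission by 2.06 ± 0.38 (adjusted p 0.000938), P2ry12 by 1.82 ± 0.45 (0.0114) and Fcrls by 1.60 ± 0.43 (0.0159); 5 of 11 homeostatic genes rose (6 adjusted over the list alone, 8 under quantile normalization, median 0.79). Saa3 fell by 2.62 ± 0.47, Fcna by 1.90 ± 0.34, the scavenger receptor gene Marco by 1.93 ± 0.45 and the interferon regulator genes Irf1 and Irf7 by 1.35 ± 0.35 and 1.32 ± 0.34. Of 16 interferon gamma genes 10 fell (13 adjusted over the list alone, 3 under quantile normalization, median -1.22) and of 14 type I genes 4 (9 and 1). None of the 10 disease-associated or 16 proliferation genes was called by limma, while 1 of 11 MHC class II genes and 3 of 16 class I genes (5 adjusted over the list alone, 0 of either under quantile normalization) were lower. H2-Aa (-0.25 ± 0.43) and Cd74 (-0.09 ± 0.50) did not differ, and both turned positive under quantile normalization (0.0095 and 0.062) and without remission 7 and 8 (0.064 and 0.27). The replicate block gave the same values as leaving these 2 libraries out. Numbers 7 and 8 occur only in remission, so the block takes them out of this estimate. Cd74 was positive without remission 7 or 8 or max 1, 2 or 3 as well, at 0.0030 to 0.13. Border macrophage genes fell for 2 of 7.

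The totals of 31 higher and 119 lower in remission than at max, or 56 and 39 under quantile normalization (median shift -0.29), rest on few libraries. Without 1 library the count fell to 44 (remission 7), 55 (max 4), 74 (remission 8), 82 (max 2), 86 (max 1) or 97 (remission 6), and 24 of 36 called genes under the naming rule lost their call. Remission 7 and 8, whose inputs lay with cure and relapse, carried many of the calls: without both, 17 genes were called, and with the side of the split as a term 21, Gp9 (2.11, adjusted p 0.00413) and Saa3 (-2.12, 0.00413) among them but not P2ry12 (1.40, 0.0675), Fcrls (1.59, 0.052), Irf1 (adjusted p 0.0814) or Irf7 (-1.05, 0.0691). Marco kept its call with that term but lost it without both libraries (0.0546).

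Most genes called for cure against remission were lower in cure. Saa3 was lower in cure by 2.28 ± 0.49 (adjusted p 0.00515), the secreted glycoprotein gene Lgals3bp by 1.88 ± 0.39, Ccl5 by 1.78 ± 0.42, the interferon-induced gene Ifit3 by 1.67 ± 0.39 and H2-K1 by 1.06 ± 0.25. Of 11 MHC class II genes 7 fell (9 adjusted over the list alone), of 16 class I genes 9 (10), of 14 type I interferon genes 9 (11) and of 16 interferon gamma genes 5. Of 244 called genes only 3 were higher, among them Rpl39, a ribosomal protein gene (chromosome X, 37082520 to 37085402, minus strand), and Gpr34 (chromosome X, 13632089 to 13640858, plus strand). Rpl39 stood at 93.1 ± 65.8 in cure (n = 5) against 11.5 ± 8.75 in remission (n = 8; 2.82 ± 0.55, adjusted p 0.00515) and Gpr34 at 24.2 ± 18.2 against 3.66 ± 1.93 (2.11 ± 0.56, 0.0107). The background levels of Rpl39 were high, at 89.1 ± 49.3 in remission and 34.0 ± 33.6 in cure in the IgG libraries, above the anti-HA mean in remission.

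Many calls of this decline rested on single libraries. Whether they rest on scaling cannot be decided. Quantile normalization removes a decline that most of the chosen genes share, and left a median log2 fold change of 0.0046. Quantile normalization left 4 genes higher and 3 lower (median shift -0.59), with no call in the class I, class II or interferon lists and H2-D1 and Psmb10 turning positive; it ended the calls of H2-K1 (-0.20), Ccl5 (-0.98) and Ifit3 (-1.16). The count went from 244 to 25 without cure 3, 105 without cure 2, 157 without cure 4 and 425 without cure 5, and 35 of 43 called genes under the naming rule lost their call without 1 library. C3, Cfb, Cd74 and H2-Aa were lost without cure 2 (adjusted p 0.0672, 0.0595, 0.0663 and 0.114) or cure 3 (0.0730, 0.0730, 0.0797 and 0.0974), and H2-Ab1 without cure 3 (0.056). Fitting only the compared groups gave 25 genes and ended the call of H2-K1 (0.0511). With the side of the input split as a term no gene was called (adjusted p 0.998 for Saa3 and Gpr34 and 0.356 for Rpl39), although Rpl39 and Gpr34 kept their size (3.16 and 2.15) and Saa3 fell to -0.77.

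**Figure D2:**
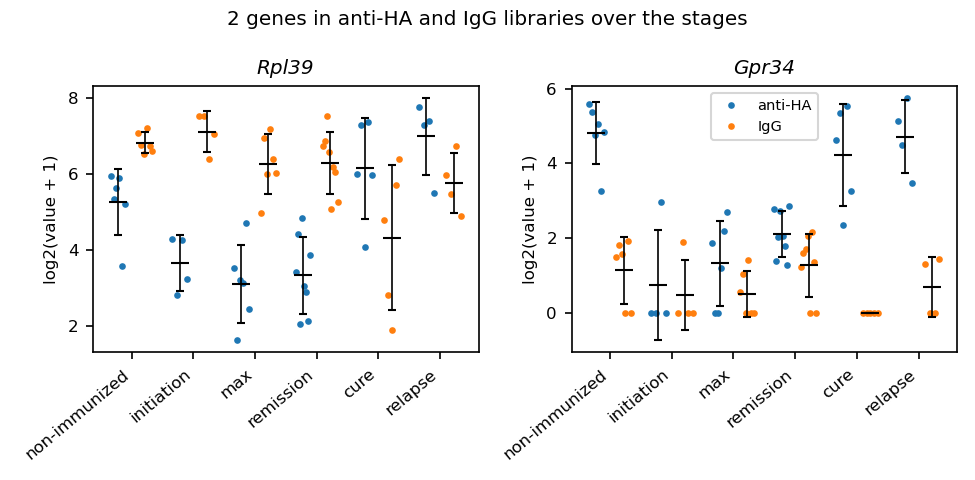
Deposited values of Rpl39 and Gpr34 (y axes) in anti-HA and IgG libraries of the 6 stages (x axes); points are libraries and bars are the mean ± SD. In anti-HA libraries Rpl39 averaged 11.5 in remission and 93.1 in cure, while its IgG background averaged 114.4 in non-immunized mice.

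Relapse was compared with cure and with max. Against cure, limma called 0 genes, with 23 below an unadjusted p of 0.05; edgeR called 0, with 19 unadjusted. Without cure 5, limma called 1 gene, and library weights gave 116. The differences of Cd74 (0.70 ± 0.62), H2-Aa (0.50 ± 0.53), Ccl5 (0.60 ± 0.49) and the complement gene C4b (0.89 ± 0.41) all had an adjusted p of 0.952; H2-Aa turned to -0.072 under quantile normalization and C4b passed with library weights (0.00926).

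Most genes called for relapse against max were lower in relapse. All 16 interferon gamma genes were lower in relapse (median -2.09, 11 under quantile normalization), as were 13 of 14 type I genes (-1.94, 8). The guanylate-binding protein gene Gbp8 was lower by 3.53 ± 0.75 (adjusted p 0.000869), the immune-responsive gene Irg1 by 3.23 ± 0.73, Cfb by 3.09 ± 0.64, Cxcl10 by 2.68 ± 0.65, Irf7 by 2.46 ± 0.40, Ccl5 by 2.46 ± 0.47 and Cd40 by 1.90 ± 0.47. Of 16 MHC class I genes 11 were lower and of 11 class II genes 6, or 1 of each under quantile normalization, where H2-D1, Tap2 and Tapbp turned positive. H2-Ab1 was lower by 2.13 ± 0.59, a call that quantile normalization ended (0.0516). H2-Aa was not called (-1.09 ± 0.51, adjusted p 0.0694), except without max 6 (0.0442), with library weights (0.0178) or in a fit of the compared groups alone (0.0258). Disease-associated genes differed for 3 of 10 (2 adjusted over the list alone, 0 under quantile normalization); Apoe (-0.03), Spp1 (0.77) and Itgax (-0.53) did not pass. Apoe was positive without relapse 2 (0.046), relapse 3 (0.058) or max 4 (0.031), and Itgax under quantile normalization (0.20). Higher in relapse were Rpl39 (146.6 ± 72.8 against 9.64 ± 8.07, 3.90 ± 0.62, adjusted p 0.000176), Gpr34 (3.39 ± 0.63), P2ry12 (2.37 ± 0.54) and Gp9 (1.71 ± 0.46), and 4 of 11 homeostatic genes (8 under quantile normalization). The totals were 31 higher and 352 lower, or 89 and 85 under quantile normalization (median shift -0.68). Every relapse library and no max library lay on the cure side of the input split. With that side as a term, again estimated from remission libraries alone, 0 genes were called by limma. The differences of Irf7 (-1.40), Ccl5 (-1.31), Cxcl10 (-1.54) and P2ry12 (0.70) shrank, while Rpl39 (4.35) and Gpr34 (3.44) did not. The absence of calls does not show that a batch explains the differences. Over all stages 697 of the 716 genes differed in at least 1 stage by limma, 538 under quantile normalization and 704 by edgeR.

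Microglia of Ifngr ko/fl mice, labelled with a null and a floxed allele of the interferon gamma receptor, were compared with ko/wt microglia to ask what the receptor controls in them during EAE. The targeted gene came first. Ifngr1 (chromosome 10, 19591949 to 19610229, plus strand) was at 299.9, 304.6, 299 and 232.1 in the ko/wt anti-HA libraries and at 80.99, 88.37, 127.1 and 76.67 in ko/fl, a log2 fold change of -1.62 ± 0.24 (limma, n = 4 and 4, adjusted p 0.000358). In IgG libraries it was at 11.9 ± 6.71 in ko/fl and 15.2 ± 6.69 in ko/wt, and in inputs at 14.4 ± 4.73 and 18.3 ± 4.99.

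Of the lists tested, MHC class II genes had the lowest median change in ko/fl microglia. All 8 measured members fell (median -3.10; 8 under quantile normalization): H2-Aa from 15670 ± 6975 to 1284 ± 140 (-3.50 ± 0.34, adjusted p 0.000139), Cd74 from 35210 ± 19510 to 3327 ± 918 (-3.27 ± 0.42), H2-Ab1 by 3.33 ± 0.37, H2-Eb1 by 3.22 ± 0.37 and their transactivator gene Ciita by 2.99 ± 0.57. The inputs showed no such gap in H2-Aa, at 882.4 ± 560 in ko/fl and 887.3 ± 343 in ko/wt, nor did the IgG libraries, at 342.6 ± 107 and 452.6 ± 183; these were not tested. All 16 MHC class I genes fell as well (median -1.35; 10 under quantile normalization, where H2-K1 turned positive), with Nlrc5 at -2.41 ± 0.29, Tap1 at -1.96 ± 0.24, the non-classical class I gene H2-T23 at -1.86 ± 0.22 and the immunoproteasome gene Psmb9 at -1.65 ± 0.20. All 23 interferon gamma genes fell (median -2.16, 20 under quantile normalization), Gbp2 by 3.26 ± 0.71 and the cytokine signalling suppressor gene Socs1 by 2.51 ± 0.28. That list includes the targeted gene Ifngr1 itself and shares Ciita, Tap1 and Psmb9 with the MHC lists above. The 3 type I interferon genes in the table fell too (median -1.35; 2), Stat2 by 1.08 ± 0.22 and Oas3 by 1.35 ± 0.32, the latter not called under quantile normalization (-0.36).

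Chemokine genes went both ways in ko/fl microglia. Cxcl9 fell from 43.1 ± 18 to 1.72 ± 2.03 (-4.30 ± 0.57), Cxcl11 by 2.77 ± 0.44, Ccl5 by 2.18 ± 0.56 and Cxcl10 by 1.65 ± 0.30, while the inflammatory chemokine genes Ccl3 and Ccl4 rose by 1.45 ± 0.27 and 1.11 ± 0.35; of 8 measured, 3 rose and 5 fell. Complement genes were lower for 4 of 5, such as Serping1 (-1.88 ± 0.46), Cfb (-1.56 ± 0.26) and C4b (-1.33 ± 0.24), and Cfp, which encodes properdin, was higher (0.97 ± 0.21). Spp1 rose from 340.1 ± 144 to 3812 ± 1864 (3.47 ± 0.39, adjusted p 0.000139), with inputs at 82.1 ± 24.4 and 201.5 ± 103. Fcrls rose from 301.3 ± 168 to 1438 ± 378 (2.41 ± 0.43), the arginase gene Arg1 by 2.22 ± 0.58, the proteoglycan gene Cspg4 by 2.86 ± 0.61 and the haptoglobin gene Hp by 1.78 ± 0.39. All 4 disease-associated genes in the table rose (median 0.93; 2 under quantile normalization), Ctsd by 0.92 ± 0.27, not called under quantile normalization (0.63), and Apoe by 0.94 ± 0.28, which was 0 there. Of the 204 genes 74 were higher and 125 lower; quantile normalization gave 76 and 80 (median shift -0.58) and edgeR called 204. Adjusted over the list alone, no list count changed, and again the authors chose these genes on the same libraries. None of 42 called genes under the naming rule lost its call without 1 library, and without number 4 of both genotypes 67 were higher and 125 lower.

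**Figure D3:**
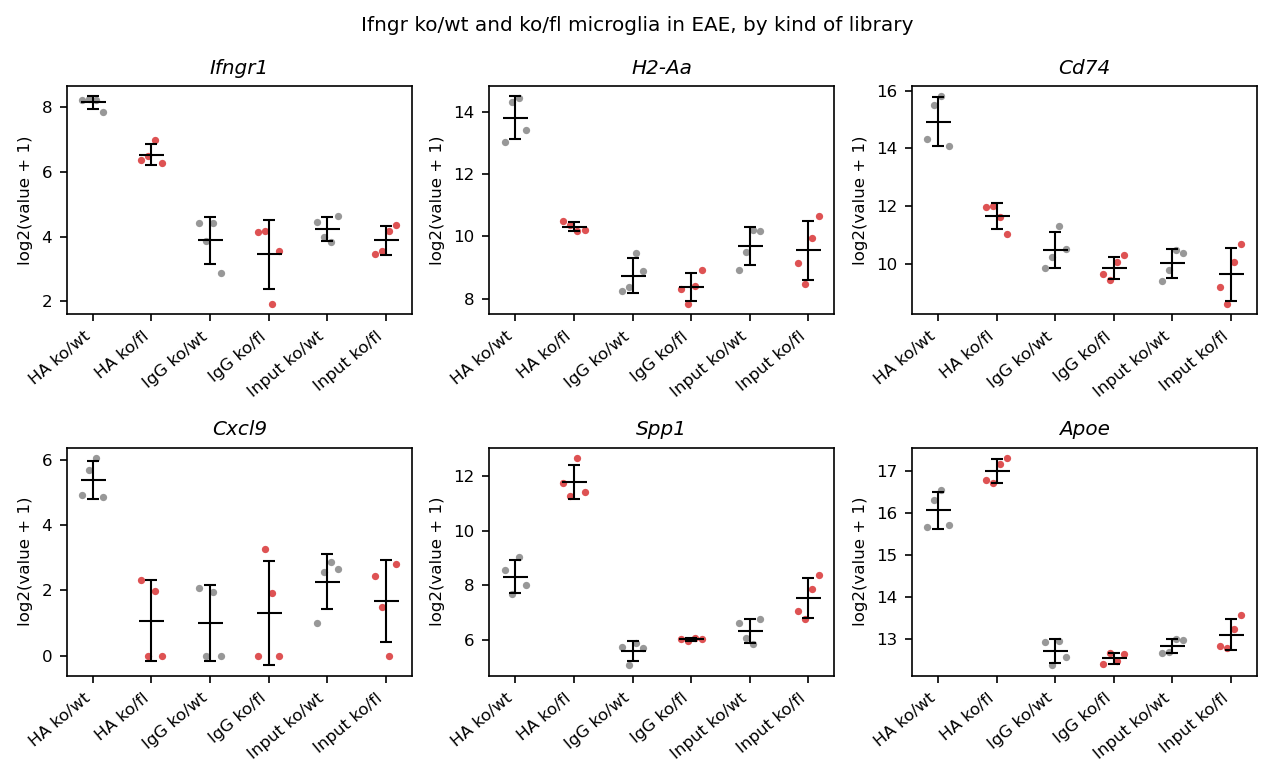
Deposited values of Ifngr1, H2-Aa, Cd74, Cxcl9, Spp1 and Apoe (y axes) in anti-HA, IgG and input libraries of Ifngr ko/wt and ko/fl mice (x axes); points are the 4 libraries per group and bars the mean ± SD. H2-Aa averaged 15670 in ko/wt and 1284 in ko/fl anti-HA libraries, and Spp1 340.1 and 3812.

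T cells of the same genotypes were compared to ask whether loss of the receptor in Cx3cr1-lineage cells changed the T cells around them. In CD25pos cells of ko/fl mice, 32 of 85 genes were higher and 48 lower (limma; 32 and 29 under quantile normalization with a median shift of -0.09, and 85 by edgeR). Higher were the lysosomal transporter gene Slc15a3 (2.15 ± 0.43, n = 6 and 5, adjusted p 0.000293), the chromatin gene Setd5 (20.6 ± 11.5 against 5.17 ± 2.26, 1.75 ± 0.33), the acetyltransferase gene Kat5 (1.89 ± 0.47), Rabep2 (1.94 ± 0.53) and Stard10 (1.69 ± 0.47). The 48 lower genes were of many kinds and included some typical of brain cells: the prostaglandin synthase gene Ptgds (5.66 ± 2.90 against 48.3 ± 65.2, -2.05 ± 0.55, adjusted p 0.00296), the neuronal enolase gene Eno2 (4.11 ± 2.46 against 16.4 ± 9.70, -1.72 ± 0.47), the neuronal nuclear protein gene Rbfox3 (-1.98 ± 0.57), the synaptic vesicle gene Syp (chromosome X, 7638471 to 7653256, plus strand; -2.16 ± 0.91, adjusted p 0.0302) and Serpinf1 (-2.13 ± 0.57). All 3 measured neuron markers were lower (median -1.98, all 3 adjusted over the list alone). Adjusted by the authors over all 8627 genes, Slc15a3 (adjusted p 0.0972), Rabep2 (0.0947), Kat5 (0.0556), Setd5 (0.0545) and Rbfox3 (0.0682) did not pass 0.05. Ptgds, Eno2 and Syp did. Syp lost its call without ko/fl 2 (0.0607), ko/fl 5 (0.0575), ko/wt 2 (0.0732) or ko/wt 3 (0.16, log2 fold change -1.10), with library weights (0.135), with a pseudocount of 0.1 (0.0688) and in a fit of the compared groups alone (0.0691). Numbers 2 and 3 of ko/wt had the highest values of 1 read, 3.47 and 2.29, and the highest neuron marker scores, 4.24 and 6.18. Without them 31 genes were higher and 33 lower. Syp (-0.31, adjusted p 0.669), Ptgds (-0.80, 0.0611), Rbfox3 (-0.90, 0.0785) and the phosphatase inhibitor gene Ppp1r14b, otherwise 1.86 ± 0.55 higher (0.57, 0.106), then lost their calls.

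CD25neg cells showed no called difference between genotypes. Limma called 0 of the 85 genes, with 8 below an unadjusted p of 0.05 and 1 called without ko/wt 1; edgeR called 0, with 10 unadjusted. Syp was at -0.58 ± 0.86 (n = 6 and 6, adjusted p 0.939) and Eno2 at -0.50 ± 0.44 (0.769). A test of whether the genotype effect differed between the gates called 39 genes, 25 with a more positive effect in CD25pos cells and 14 with a more negative one (28 and 13 under quantile normalization, 30 and 28 by edgeR); all 85 were chosen for an effect in CD25pos cells, which favours such a difference. Kat5 (difference of effects 2.31 ± 0.65, adjusted p 0.00856) and Setd5 (2.03 ± 0.46, 0.00286) had more positive effects, and the helicase gene Supv3l1 (-2.56 ± 0.66), the lysosomal lipase gene Lipa (-1.54 ± 0.39) and Rbfox3 (-2.29 ± 0.79, 0.0256) more negative ones. The Rbfox3 call was lost without CD25pos ko/wt 2 and 3 (-1.21, 0.0888), with library weights (0.067) and with pseudocounts of 0.1 (0.0509) or 10 (0.055). Of 12 called genes under the naming rule, 3 lost their call without 1 library.

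CD25pos and CD25neg cells of ko/wt mice were compared directly, within genes chosen for the genotype contrast of CD25pos cells. The same CD25pos ko/wt libraries enter both contrasts, so the choice favours calls here too. Higher in CD25pos cells were the DNA ligase gene Lig1 (2.01 ± 0.39, n = 5 and 6, adjusted p 0.000213), Eno2 (1.90 ± 0.47), Serpinf1 (2.40 ± 0.57) and Rbfox3 (2.15 ± 0.57), the last not called with library weights (0.0795) or without ko/wt 2 and 3 (0.0525). Lower were the gamma-glutamyltransferase gene Ggt1 (-3.62 ± 0.49, adjusted p 2.38e-06), Cpne7 (-3.61 ± 0.40), Kat5 (-2.33 ± 0.47) and Setd5 (-1.68 ± 0.33). All 3 neuron markers were higher in the CD25pos gate (median 2.15). The totals were 25 higher and 28 lower (25 and 29 under quantile normalization, 39 and 26 by edgeR), and 1 of 13 called genes under the naming rule, Syp (2.17, adjusted p 0.0432), lost its call without 1 of 6 libraries: CD25pos 2 (0.0987) or 3 (0.189, log2 fold change 1.11) or CD25neg 1 (0.0799), 2 (0.0719), 4 (0.0955) or 5 (0.0575).

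**Figure D4:**
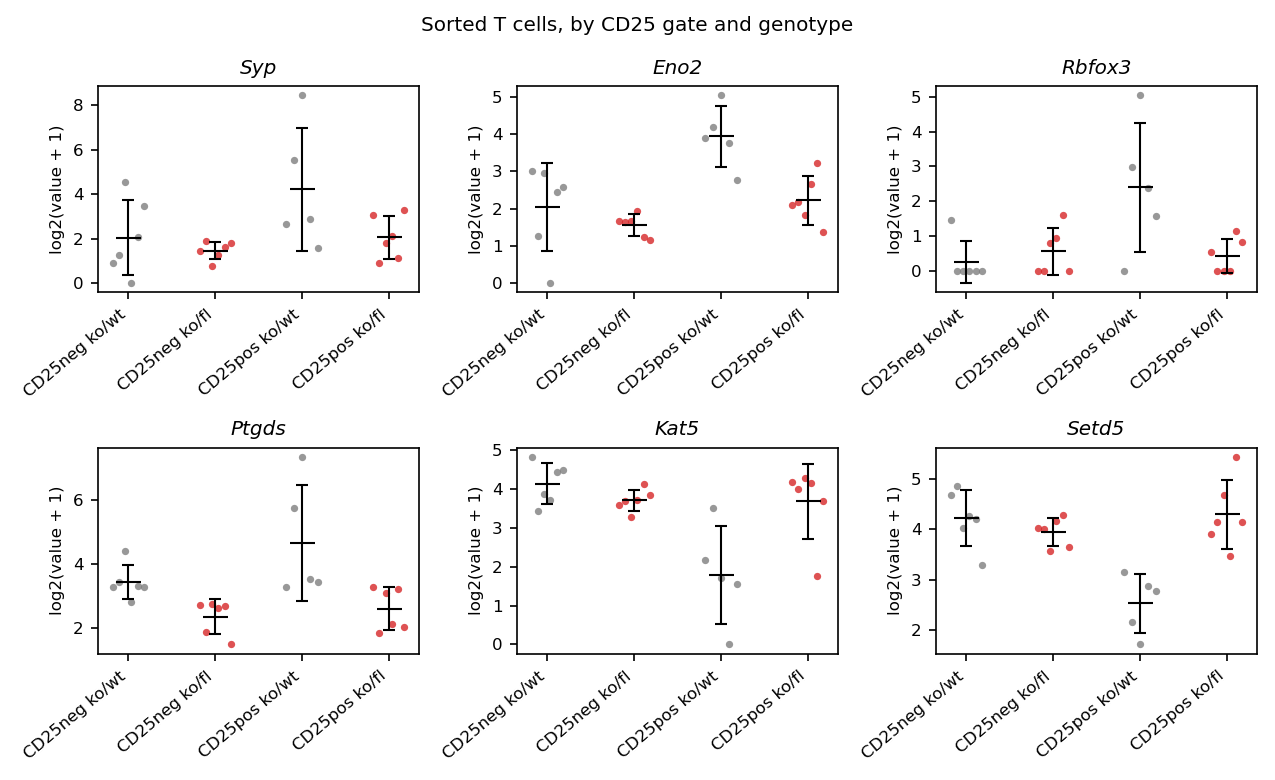
Deposited values of Syp, Eno2, Rbfox3, Ptgds, Kat5 and Setd5 (y axes) in sorted T cells by CD25 gate and Ifngr genotype (x axes); points are libraries and bars are the mean ± SD. Setd5 averaged 20.6 in ko/fl and 5.17 in ko/wt CD25pos cells, and the single highest Syp value was 348.

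The authors' deposited table of all 8627 genes gave the genotype contrast of CD25pos cells without prior choice of genes. At an adjusted p of 0.05, the authors' deposited table gave 3 genes higher and 15 lower in ko/fl. Higher were the histone gene H3f3a (log2 fold change 1.17, adjusted p 0.0173), the centromere gene Cenpv (4.18, 0.0204) and Mpnd (1.36, 0.034), and lower among others Syp (-4.31, 0.0319), Ptgds (-3.07, 0.0118), Eno2 (-2.02, 0.0234) and the G protein gene Gnai2 (-0.47, 0.00225), per the authors' deposited table. Genes tied to regulatory T cells did not pass in the authors' deposited table: Foxp3 was at -0.21 (0.821), Il2ra at -0.81 (0.404), Ctla4 at 0.05 (0.962) and Il10 at 0.15 (0.935). Nor did the effector cytokine gene Ifng in the authors' deposited table (1.48, 0.32).

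Of 39 lists tested over the authors' deposited table, neuron markers alone passed: all 7 measured genes were lower in ko/fl (median log2 fold change -2.02, cameraPR p 0.000309, adjusted p 0.012, percentile 0 among random lists). The p takes the genes of a list as nearly independent, by the preset correlation of 0.01, and does not measure the spread between libraries. Among the chosen T cell genes, neuron marker scores were highest in CD25pos ko/wt 2 and 3 (4.24 and 6.18). Astrocyte markers were lower for 3 of 3 (median -2.72, adjusted p 0.0649) and oligodendrocyte markers for 4 of 4 (-0.59, 0.456), short of the threshold. The regulatory T cell core (19 genes, median -0.10) and the Th1 (0.34), Th17 (0.36) and chemokine (0.68) lists had an adjusted p of 0.456, as did the disease-associated microglia (0.35) and microglial contamination lists (0.38), and effector regulatory T cell genes (-0.08) one of 0.868. Interferon gamma genes were at a median of 0.26 (0.58), type I interferon genes at -0.0037 (0.936), MHC class I genes at -0.03 (0.868) and class II genes at 0.20 (0.87). Proliferation genes were at 0.12 (0.975), ribosomal proteins at -0.07 (0.549), nuclear oxidative phosphorylation genes at -0.0057 (0.914), the proteasome at 0.05 (0.914) and T cell markers at -0.12 (0.868). Adjusted p for the other 20 lists tested ran from 0.499 to 0.917.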

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

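The counts over other splits of the libraries were fixed before the data were examined; the swaps within pairs, the tests of explanations for brain-cell transcripts, for the split of the inputs and for Rpl39 and Gpr34 were chosen only after the results were seen, as were the genes tested for single libraries that stand apart.

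Dixon's criterion was applied 142 times, each to 1 quantity in 1 group of 4 to 8 libraries, and 13 times a library stood far from the others of its group. The criterion's nominal rate of about 1 in 20 is no benchmark here. It assumes normal values, single genes were tested without a log, and the same libraries recur. Non-immunized 5 was low in the mean log2 value of MHC class I genes, at 7.21 against 7.74 to 7.91 in the others, and high in Spp1, at 225.6 against 26.2 to 58.7. Its input had a low value of 1 read, 0.808 against 0.935 to 1.01. Max 2 was low in disease-associated genes, at 9.93 against 10.49 to 10.77, and cure 3 in border macrophage genes, at 5.14 against 6.43 to 6.80. Cure 5 was high in Saa3, at 1912 against 151.9 to 631.5, and in Cxcl10, at 685.7 against 34.2 to 115.4. Initiation 2 had Cd74 at 43130 against 2537 to 5364, and initiation 3 had Spp1 at 265.8 against 132.1 to 151. Relapse 3 had P2ry12 at 430.5 against 194.7 to 230.8, and max 5 had Rpl39 at 24.96 against 2.07 to 10.4. Ifngr ko/wt microglia 4 had Ifngr1 at 232.1 against 299 to 304.6, still above each ko/fl library. CD25pos ko/wt 3 had Syp at 348 against 1.96 to 45.1.

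The effect of the genotype differed between the CD25 gates for 39 of 85 genes by the interaction term of limma, among them Kat5 (2.31 on the log2 scale), Setd5 (2.03) and Rbfox3 (-2.29); the genes were chosen for an effect in CD25pos cells, so the count is no independent evidence. In the IgG libraries, which enter no comparison of stages, Rpl39 averaged 114.4 in non-immunized mice, above its means of 42.5 in anti-HA libraries and 2.48 in inputs of those mice.

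Some brain-cell transcripts were lower in CD25pos T cells of ko/fl mice. Fewer reads in the ko/wt libraries stay open as a cause. The 2 ko/wt libraries with the highest value of 1 read, numbers 2 and 3, were left out. Only 1 of 4 called markers, Eno2, then kept its call (-1.72 ± 0.47 before, -1.26 ± 0.52 after), while Syp, Rbfox3 and Clu lost theirs as their size fell. These 2 libraries also had the highest neuron marker scores (4.24 and 6.18), and number 3 the most Syp. Leaving them out removes the brain-cell transcripts themselves, so it cannot decide on depth. RNA of neurons and glia carried into the ko/wt sorts may account for the lower transcripts: 100% of the 14 measured markers of neurons, astrocytes and oligodendrocytes were lower in ko/fl in the authors' deposited table. Microglial genes did not go that way. Of the 12 genes of the microglial contamination list, 10 were higher and 2 lower in ko/fl there (median 0.38), and the list did not pass. Carry-over of RNA of all brain cells alike would have made them lower. Of the 14 markers, 4 were among the chosen T cell genes, Thy1 and Mal are also expressed by T cells, and the gate on T cells should remove brain cells but not free RNA. A lasting difference between the genotypes stays open as the biological explanation and was not tested.

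The inputs fell apart on principal component 3, which held 4.02% of their variance: remission 7 and 8 lay with all of cure and relapse, and remission 1 to 6 with the other stages. It was noticed among 5 components in each of 3 kinds of library, and a similar parting reached a separation of 0.963 in the IgG libraries and of 0.942 on component 2 of the anti-HA libraries, with 13.31% of their variance, where remission 7 and 8 lay at 12.7 and 12.07 and remission 1 to 6 at -4.43 to 10.99. Depth stays open as a cause, since log2 of the value of 1 read was -1.40 and -1.12 in remission 7 and 8 against -0.85 to 0.28 in remission 1 to 6. Single inputs go against it: max 3 (-1.04, score 0.75) and remission 1 (-0.85, 0.16) lay on the other side, with lower values of 1 read than cure 1 (-0.66, 6.69), cure 5 (-0.56, 4.94) and relapse 2 (-0.67, 3.89). Within sides the relation was too uncertain to decide, as on the other side the score followed that value at r = -0.162, an absolute r of 0.162 (n = 22, permutation p 0.476, rho -0.04, r 0.30 without the 2 farthest libraries) and within the cure side at r = 0.14 (n = 11, p 0.686, rho 0.04, r 0.14 without the 2 farthest; adjusted p 0.686 for both). A shared batch of libraries or mice could explain the gap of 3.66 between remission 7 and 8 and the nearest of remission 1 to 6, but it cannot be told apart from disease stage, because all of cure and relapse lie on 1 side. A later time within the disease course is a biological alternative that was not tested.

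Rpl39 and Gpr34 were higher in anti-HA libraries of cure than of remission by a mean of 2.47 on the log2 scale (SD 1.34 over 5 cure and 0.69 over 8 remission libraries), against the decline of most called genes. The values argue against the split of the inputs as the whole cause. Remission 7 and 8 differed from remission 1 to 6 by -0.25 (SD 0.62 over 1 to 6). That rests on 2 libraries with low values of 1 read (0.480 and 0.518), so a part played by the split stays open. For Rpl39 the values also argue against the same change in the whole brain. Its inputs of cure and remission differed by 0.28 (95% interval -0.70 to 1.27) against 2.82 in anti-HA libraries. For Gpr34 that stays open, at -0.12 with a median of 0 reads in these inputs. Depth may contribute: within stages the mean of the 2 genes followed the value of 1 read (r = 0.38, rho = 0.34, n = 33, permutation p 0.0356 and 0.0655; r = 0.41 without the 2 farthest libraries). Yet the median value of 1 read was lower in cure (0.735) than in remission (1.30), which by that relation would give lower values in cure. The disease stage stays open as the biological explanation, and the high IgG background of Rpl39 is a further reason for caution.

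Other splits of the same libraries were used to ask whether chance could be excluded. For anti-HA against input at max and in remission the real split stood alone, also among swaps within pairs. The authors' deposited columns also compare anti-HA with input. Whether genes were chosen on those columns too is not known, so chance was not excluded there either. Few splits called as many genes as the real one: 1 of 100 splits in non-immunized mice (598 genes, highest other 518), 1 of 100 at max (671, 643), 1 of 100 in remission (685, 662), 2 of 100 in cure (597, 602) and 1 of 35 in relapse (613, 469). Where the numbers were taken to pair the libraries, labels were also swapped within pairs: the real split alone called as many genes among 32 swaps at max (671, highest other 643) and among 100 of 128 in remission (685, 683). In non-immunized mice, cure and relapse no such swaps were run. Same-numbered libraries correlated there at medians of 0.12, 0.22 and 0.12, against -0.02, -0.02 and -0.04 for other numbers. Pairs may thus hold there too, and chance was not excluded. In relapse, 4 pairs leave only 8 splits that part every pair. At initiation 1 of 35 splits reached the count (675, 585), but the pairs allow only 8 swaps (675, 562), too few for a share under 0.05. Splits that parted fewer pairs called at most 585, 632 and 662 genes at initiation, at max and in remission.

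For comparisons whose genes the authors chose on the same groups, the splits cannot exclude chance, since the choice favours the real split. There 1 of 100 splits, the real one, reached the count for initiation (649, highest other 440), max (635, 490), remission (555, 259), cure (297, 214), relapse (327, 164), any stage (697, 90), remission against max (150, 131), relapse against max (383, 197), CD25pos T cells (80, 61), the CD25 gates (53, 35) and the interaction (39, 9), and 1 of 35 splits for Ifngr microglia (199, 0). Chance was not excluded for cure against remission, with 5 of 100 splits (244, highest other 490, which points to a structure of the libraries beyond these stages). For relapse against cure, 100 of 100 splits (0, 32), and CD25neg T cells, 100 of 100 splits (0, 1), a real count of 0 is reached by every split, so these say nothing.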

How the results depend on the processing

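The fits by edgeR, with the input split as a term, or without remission 7 and 8, without CD25pos ko/wt 2 and 3, without number 4 of both genotypes or without the IgG libraries with the fewest reads were chosen only after the data were seen. Over 323 printed gene results and all settings, 7340 of 7711 values kept direction and side of the threshold, 302 lost the call, 23 gained it and 46 reversed; over everything the naming rule picked these were 24967, 1281, 60 and 276 of 26584. Limma with trend and robust settings, the filter on low means, the fits without the 2 IgG libraries and without number 4 of both genotypes changed none of the 323, 269, 26 and 39 gene results they covered. Apart from leaving out 1 library, 239 of 268 counts stayed within 1.5 times. Camera with an estimated correlation and a filter on means in the authors' deposited table could not be run, since that table holds no values per library and no mean. For the values that follow, the cause was not tested except where the setting itself is stricter or leaves out libraries.

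Quantile normalization moved the called genes to 372 at initiation, 396 at max, 368 in remission, 95 for remission against max, 7 for cure against remission, 174 for relapse against max, and 387 and 412 for anti-HA against input at initiation and max. It reversed Mki67 at max (-0.019), remission (-0.31), cure (-0.50) and relapse (-0.047), Kif11 in remission (-0.048), Mcm3 in relapse (-0.17), H2-Aa (0.0095) and Cd74 (0.062) for remission against max, H2-Aa for relapse against cure (-0.072), Itgax for relapse against max (0.20), and P2ry12 (-1.21) and Cxcl10 (-1.10) for anti-HA against input at max. An adjusted p of 0.01 left 15 genes for remission against max, 33 for cure against remission, 241 for relapse against max, 34 for the CD25 gates and 19 for the interaction, and 1 of 18 genes in the authors' deposited table. A fold of at least 2 left 335 in remission, 68 for remission against max, 94 for cure against remission and 246 for relapse against max. Fitting only the groups compared gave 25 for cure against remission and 35 for the CD25 gates. Library weights gave 497 for cure against remission and 116 for relapse against cure, and reversed Apoe at initiation (-0.22), Cd74 (0.19) and Spp1 (-0.10) for remission against max. By edgeR Mcm3 in cure was at 0.11.

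The replicate block gave 16 genes for remission against max and 399 for cure against remission, and reversed H2-Aa (0.064) and Cd74 (0.27) for remission against max; the numbers do not pair libraries of different stages, genotypes or T cell gates by the correlation of deviations, so a call lost under the block is no weaker effect there. No other count moved by over 1.5 times under the block, and of 323 gene results 14 lost and 2 gained a call. Without remission 7 and 8 the counts were 17 for remission against max and 391 for cure against remission, with H2-Aa at 0.064 and Cd74 at 0.27 for the former. With the input split as a term they were 21 for remission against max and 0 for cure against remission and for relapse against max. For remission against max, the block, leaving out remission 7 and 8, and the split term all take these 2 libraries out of the estimate. Their equal fold changes are therefore not separate support. That term reversed H2-Aa (0.064) and Cd74 (0.27) for remission against max, P2ry12 (-0.50) and Spp1 (-0.24) for cure against remission, H2-Ab1 (0.058), H2-Aa (0.19), Cd74 (0.38), Apoe (0.49), Itgax (0.11) and Spp1 (-0.36) for relapse against max, and Mcm3 in cure (0.86).

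Leaving out 1 library, 255 of 267 counts stayed within 1.5 times. The count for remission against max ran from 44 to 188, for cure against remission from 25 to 425, and for relapse against cure and CD25neg T cells from 0 to 1. Of 1008 called genes under the naming rule 114 lost their call without 1 library. Of 3690 values of printed genes 118 lost the call, 4 gained it and 15 reversed: Apoe at initiation (-0.38 to 0.22), Apoe for relapse against max (-0.13 to 0.058), Cd74 (-0.37 to 0.13) and Spp1 (-0.060 to 0.65) for remission against max, and Mcm3 in cure (-0.34 to 0.17).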

Other observations

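The comparison of the stage and genotype tables described here, and the Fisher test on it, were chosen only after the results were seen; the authors' clusters are described as deposited.

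The authors' deposited clusters of the 716 stage genes follow 6 courses. The cluster of 124 genes held all 11 homeostatic genes, with median log2 fold changes from non-immunized mice of -1.19 at initiation, -1.34 at max, -0.92 in remission, -1.25 in cure and -1.15 in relapse. The cluster of 292 genes held all 16 proliferation genes and peaked at initiation, with medians of 1.58, 1.08, 0.76, 0.19 and 0.38. That of 262 genes, with 13 interferon gamma and 7 disease-associated genes, peaked at max (1.34, 1.85, 1.20, 0.59 and 0.82). A cluster of 23 genes stayed up longer, at 0.71, 1.30, 1.37, 1.01 and 0.88, and one of 14 genes was highest in relapse, at 0.61, 0.87, 0.87, 1.08 and 1.75. Spp1 formed a cluster alone, at 1.55, 2.65, 2.98, 3.58 and 3.41. Genes for cholesterol and lipid handling were called higher for 2 of 4 at initiation, all 4 at max, in remission and in cure, and 3 in relapse, where 4 were adjusted over the list alone (1, 3, 2, 3 and 3 under quantile normalization).

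A hypothesis drawn from the data was that genes lower in Ifngr ko/fl microglia are those higher at max of the disease course. The tables share 115 symbols, of which 109 were called in both. Of 85 genes lower in ko/fl, 85 were higher and 0 lower at max (limma; 79 and 5 under quantile normalization), and of 24 genes higher in ko/fl, 12 were higher and 12 lower (11 and 13), a difference with p 8.63e-10 by Fisher's exact test across genes, two-sided. Genes are not independent replicates and both tables hold chosen genes, so the p may be far too small, and the test does not show that the receptor drives the changes of the disease course. Among the genes higher in ko/fl and lower at max were Fcrls, Gp9, Abcb4 and Rpl39, and among those higher in both were Spp1, Apoe, Ccl3 and Ccl4.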
